A study of Homo sapiens with 62 samples.

How the data were processed

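The series profiled microRNAs (miRNAs), short regulatory RNAs, in blood plasma from 12 samples of early osteoarthritis (OA), 6 of early rheumatoid arthritis (RA) and 44 of controls with neither disease. Per the labels' protocols, blood was drawn into EDTA tubes and spun, RNA was taken from 250 µL of plasma with a QIAGEN serum and plasma kit, and libraries were made with the QIAseq miRNA kit. The authors deposited 1 table of whole-number counts per miRNA and sample. Per the submitters' processing notes edgeR 3.40.2 was used, with no role given. The aligner, the counting rule, the miRNA reference, the use of strand and the use of molecular identifiers are not given in the sources used here. The table has no coordinates. Hairpin positions below come from GENCODE release 29 on GRCh38.

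The table held 2656 miRNA names and 1 blank line with no name and 0 counts, which was left out. Of the names, 1117 had no count in any sample. Every column matched the title of 1 sample, and 0 columns were left over. The total count per sample ran from 135734 to 6611550. The labels give 1 batch for all samples. No label ties samples of different groups to each other, and they were treated as coming from different people. The p-values measure the spread between these samples. In each group 0 columns were identical, and the smallest chi-square per degree of freedom between 2 libraries was 22.1 in controls, 21.9 in early OA and 53.2 in early RA, so no library was counted as a repeat of another.

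Counts were tested with edgeR 4.0.16 in R 4.3.3. The function filterByExpr, given the 3 groups, kept 370 miRNAs, which hold 99.96% of all counts. TMM factors scaled the libraries. All 3 groups entered 1 quasi-likelihood fit with robust settings, and each pair of groups was a contrast of it. All tests are two-sided. Adjusted p-values are Benjamini-Hochberg values, with a threshold of 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. Normalised counts per 1e6 (CPM) use the TMM-scaled library size, so they need not add up to the same total in every sample.

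The 18 lists of miRNAs, each with at least 3 tested members, were tested with camera from limma 3.58.1 and its preset correlation of 0.01. They cover circulating early knee OA candidates, cartilage and chondrocyte, rheumatoid arthritis literature, erythrocyte, platelet, myeloid, lymphocyte, liver, muscle, neural, epithelial, and vascular and mesenchymal miRNAs. The others are the let-7 and miR-98 family, the miR-17-92 cluster and its paralogs, the miR-29 family, the miR-30 family, the 14q32 imprinted cluster and inflammation-responsive miRNAs. Some miRNAs are in more than 1 list. For example, miR-363-3p is in the erythrocyte and miR-17-92 lists, miR-223-3p in the platelet and inflammation-responsive lists, and miR-199a-5p in the platelet and OA candidate lists. The list tests are therefore not independent of each other. Single values per sample were compared as the difference of group means by permutation, exactly for comparisons with early RA and with 100000 resamples for early OA against control, and adjusted over 12 tests. The haemolysis index is the log2 ratio of miR-451a, which red cells hold in large amounts, to miR-23a-3p, with 0.5 added to each count. A miRNA was called detected in a sample at 10 counts or more.

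The lists, the tests, the other settings and the rule for naming miRNAs were chosen before the data were examined. For each comparison the rule takes up to 12 miRNAs with the smallest p among those higher and up to 12 among those lower at the threshold. Where fewer than 5 pass, it takes the 10 with the smallest unadjusted p, given as values that do not pass. It also allows every tested member of the circulating early knee OA candidate, cartilage and chondrocyte, and rheumatoid arthritis literature lists, and the 10 most abundant miRNAs. From each other list it allows the members that pass and up to 4 more with the highest mean abundance. Placental miRNAs are never named.

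The steps were run on simulated counts with the real dispersions, group sizes and library sizes and the control means, with 200 of the 370 miRNAs changed in each of 5 simulated sets per comparison. For early OA against control, 36.8% of changes of 1.5-fold, 76.2% of 2-fold and 97.9% of 4-fold were called, and 4.64% of the calls were false. For early RA against control these shares were 21.1%, 64.3% and 93.3%, with 2.31% false. For early RA against early OA they were 14.6%, 47.9% and 89.7%, with 0.789% false. In these sets as many miRNAs were raised as lowered, and each miRNA was drawn independently. The real early OA calls were 95 higher and 195 lower, so these shares need not hold for the real data.

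Other settings tried were RLE, upper-quartile or no scaling factors, no filter or a filter at 10 CPM in 6 samples, DESeq2 1.42.0, and limma-voom with sample quality weights. Further ones were a fit of only the compared groups, the haemolysis index or the log2 total count as a covariate, the sample number as a replicate block, and each early OA or early RA sample left out in turn. List tests were also run with an estimated correlation and with fry, which tests movement in 1 direction.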

Results

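Plasma miRNAs were compared between early OA, a degenerative joint disease, early RA, an autoimmune joint disease, and controls with neither. The 44 control libraries had a median total of 2224100 counts (135734 to 6611550), the 12 early OA libraries 911736 (137145 to 3482860) and the 6 early RA libraries 2060510 (444861 to 3254340).

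The most abundant miRNA was miR-16-5p, which red cells carry in large amounts. It made up 18.2% ± 6.16 of the counts in controls (SD, n = 44), 57.9% ± 6.18 in early OA (SD, n = 12) and 24.0% ± 10.1 in early RA (SD, n = 6). In controls, next came miR-126-3p, a miRNA of endothelial cells and platelets, at 11.8% ± 2.72 in controls, 2.06% ± 1.31 in early OA and 8.52% ± 2.86 in early RA (SD). In early OA it lay below miRNAs such as let-7b-5p (7.14% ± 1.35) and miR-486-5p (4.41% ± 0.933), and in early RA below let-7a-5p (9.42% ± 2.30; SD). In controls the let-7 family followed: let-7a-5p made up 9.24% ± 2.25, let-7f-5p 8.01% ± 1.76, let-7i-5p 5.93% ± 1.01 and let-7b-5p 5.62% ± 1.08 (SD, n = 44). The hepatocyte miRNA miR-122-5p made up 2.72% ± 2.55 in controls, 1.25% ± 0.880 in early OA and 1.98% ± 2.34 in early RA (SD). In GENCODE release 29 on GRCh38, a hairpin of miR-16-5p (MIR16-1) lies on chromosome 13 at 50048973 to 50049061, in an intron of DLEU2. The hairpin of miR-126-3p (MIR126) lies on chromosome 9 at 136670602 to 136670686, in an intron of EGFL7.

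Every early OA sample had a larger miR-16-5p share than every control. The difference was 39.7 percentage points (permutation test, adjusted p = 4.0e-05, from a p of 1e-05, the smallest that the resamples can give). The haemolysis index was 3.95 ± 1.78 in early OA (SD, n = 12) and -1.62 ± 1.42 in controls (SD, n = 44), a difference of 5.56 (permutation test, adjusted p = 4.0e-05, again the smallest). All 12 early OA samples lay above the control median and 10 above the highest control. In early RA the index was -0.64 ± 1.56 (SD, n = 6), a difference of 0.98 from controls (exact permutation test, adjusted p = 0.148), with 4 of 6 samples above the control median. It differed from early OA by -4.59 (exact permutation test, adjusted p = 0.000259). The indices of early RA samples 1 and 2 were 1.01 and 1.57, and those of the other 4 ran from -2.08 to -0.92. The index also depends on its denominator, since miR-23a-3p had 2 counts in early OA sample 5 and 0 in early OA sample 6. The numerator was low in some samples too, with miR-451a counts from 3 in control 4 to 2183 in early OA sample 10. Between early OA and control miR-451a alone had a log2 fold change of 2.95, less than the index difference. With miR-191-5p as denominator the ratio was -3.18 ± 0.892 in early OA and -7.97 ± 1.49 in controls (SD). The miR-16-5p share of early RA differed by 5.77 points from controls (exact permutation test, adjusted p = 0.0663). It differed by -33.9 points from early OA (exact permutation test, adjusted p = 0.000162, from a p of 5.4e-05, the smallest that the splits can give).

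**Figure D1:**
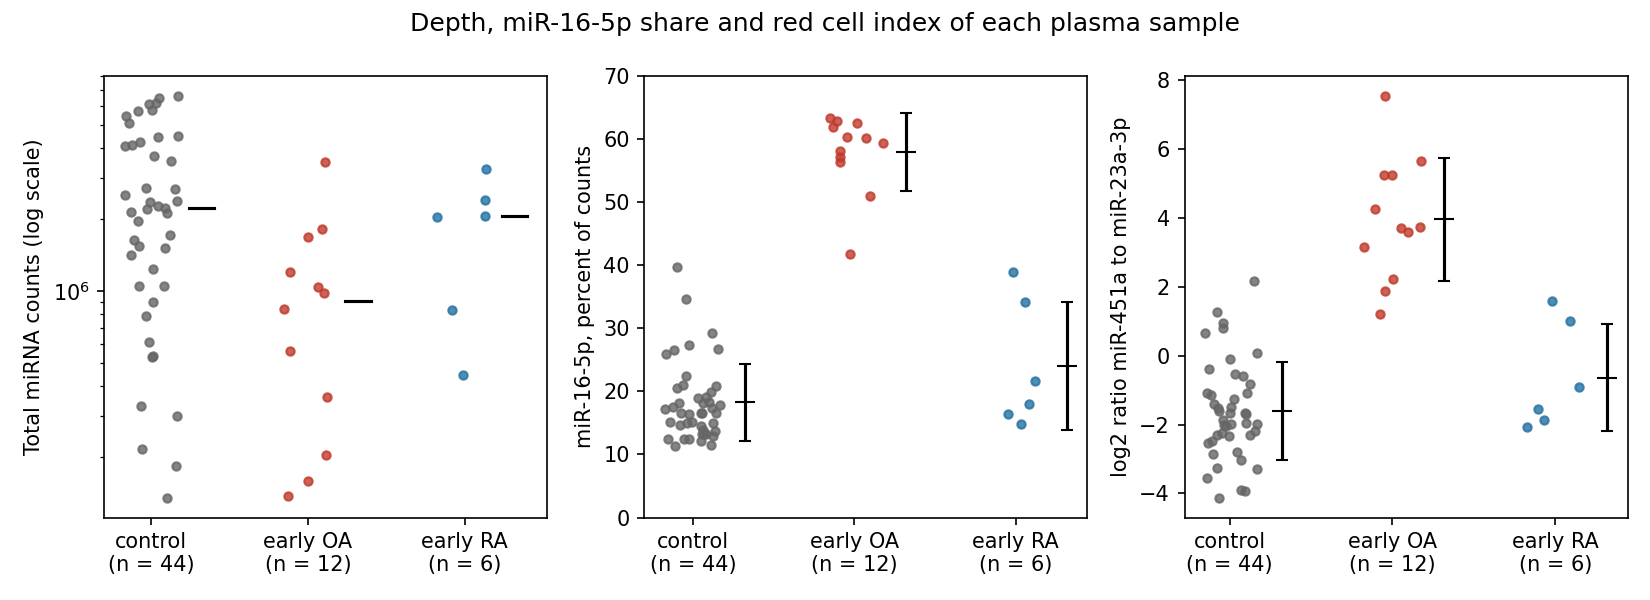
Each point is 1 plasma sample, by group: total miRNA counts on a log scale with the group median as a line, the percent of counts of miR-16-5p, and the log2 ratio of miR-451a to miR-23a-3p, the last 2 with the group mean and SD. The 12 early OA samples hold 41.7% to 63.4% miR-16-5p, and the highest control holds 39.7%.

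The log2 total count of early OA libraries differed by -1.41 from controls (permutation test, adjusted p = 0.00842, 1 of 12 above the control median). For early RA it differed by -0.26 from controls (exact permutation test, adjusted p = 0.691) and by 1.16 from early OA (exact permutation test, adjusted p = 0.148). The number of miRNAs detected was 162 ± 47.3 in early OA (SD, n = 12) and 309 ± 88.6 in controls (SD, n = 44; permutation test, adjusted p = 4.0e-05, 0 of 12 above the control median). It was 263 ± 49.8 in early RA (SD, n = 6), with adjusted p = 0.250 against controls and 0.00226 against early OA (exact permutation tests). With counts thinned to the smallest total, 135734, the means were 128.8 in controls, 91.3 in early OA and 120 in early RA.

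Between early OA and control, red cell miRNAs were higher and platelet and 14q32 cluster miRNAs lower. All 10 of 10 tested erythrocyte miRNAs were higher (10 adjusted over the list alone; median log2 fold change 2.88), beside the index difference of 5.56. They included miR-486-3p (3.36 ± 0.20), miR-486-5p (3.22 ± 0.24), miR-183-5p (3.78 ± 0.37), miR-144-3p (3.10 ± 0.37) and miR-451a (2.95 ± 0.35) (± SE, n = 12 against 44). The hairpins of the last 2 (MIR144 and MIR451A), which are transcribed in red cell precursors, are neighbours on chromosome 17 at 28861533 to 28861618 and 28861369 to 28861440. Of the platelet list 10 of 11 were lower (10 adjusted over the list alone; median -1.97), among them miR-126-3p (-1.67 ± 0.13), miR-28-3p (-2.25 ± 0.20) and miR-151a-3p (-2.00 ± 0.18). The remaining member, miR-21-5p, had a log2 fold change of -0.01 ± 0.15 (adjusted p = 0.95), but 0.47 without early RA replicate 5 or without early RA replicate 6 (adjusted p = 0.0042 and 0.00428).

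In total 290 of 370 miRNAs differed between early OA and control in edgeR's quasi-likelihood test, 95 higher and 195 lower, 247 of them by more than 2-fold. An unadjusted p under 0.05 was found for 297. The median log2 fold change of all 370 was -0.91 with TMM factors, -0.88 with RLE factors, -0.65 with upper-quartile factors and -1.96 with total counts only, no factors. With total counts only, no factors, the number of miRNAs changed was 320, 46 higher and 274 lower. Without early RA replicate 5 or without early RA replicate 6, TMM takes another reference library, and the median log2 fold change moves to -0.43, with 111 higher and 155 lower.

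The 12 higher miRNAs with the smallest p lay above the control median in 12 of 12 early OA samples. Led by miR-486-3p and miR-16-5p (2.66 ± 0.16, adjusted p = 5.9e-23), they included miR-20b-5p (2.89 ± 0.20) and miR-15a-5p (2.70 ± 0.20), a cluster partner of miR-16. The others were miR-486-5p, miR-7-5p (2.54 ± 0.19), miR-25-3p (2.04 ± 0.16), miR-1294 (2.68 ± 0.24), let-7b-5p (1.36 ± 0.12), miR-103b (1.31 ± 0.12), miR-1180-3p (3.18 ± 0.29) and miR-182-5p (2.81 ± 0.26). Normalised miR-486-3p was 24359 ± 8730 CPM in early OA (SD, n = 12) and 2379 ± 1217 in controls (SD, n = 44).

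The 12 lower miRNAs with the smallest p lay below the control median in 12 of 12 early OA samples. They were led by miR-24-3p, at 1489 ± 682 CPM against 5461 ± 857 (SD; log2 fold change -1.87 ± 0.14, adjusted p = 3.1e-19), and by miR-126-3p, at 31947 ± 14059 CPM against 101575 ± 18555. Beside the platelet members above they held miR-652-3p (-1.78 ± 0.17), miR-26a-5p (-1.83 ± 0.17), miR-28-5p (-2.53 ± 0.25), miR-744-5p (-2.35 ± 0.23) and miR-30e-3p (-2.05 ± 0.18). They also held miR-199a-5p (-2.81 ± 0.29), another member of the platelet list, and miR-181c-3p (-4.16 ± 0.35), the last with no count in 6 of 12 early OA libraries. miR-3074-5p (-1.97 ± 0.16) was the remaining one. Its hairpin (MIR3074) lies on chromosome 9 at 95086014 to 95086094, on the strand opposite to a hairpin of miR-24-3p (MIR24-1, 95086021 to 95086088).

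All 5 of 5 tested circulating early knee OA candidates were lower in early OA than in controls (5 adjusted over the list alone): miR-335-5p (-1.51 ± 0.23), miR-191-3p (-2.23 ± 0.29), miR-199a-5p (-2.81 ± 0.29), miR-671-3p (-2.81 ± 0.39) and miR-1260b. miR-1260b had no count in 10 of 12 early OA and 7 of 44 control libraries, so its fitted log2 fold change of -5.04 ± 0.71 depends on the prior count. Of 10 cartilage and chondrocyte miRNAs 3 were higher and 6 lower (3 and 6 adjusted over the list alone; 0 and 7 with no factors, so all 3 higher calls were lost there). The arms of miR-140, a chondrocyte miRNA, moved apart: miR-140-3p (0.91 ± 0.17) was higher, though at -0.09 with total counts only, no factors, and miR-140-5p (-1.30 ± 0.24) lower. Their hairpin (MIR140) lies on chromosome 16 at 69933081 to 69933180, in an intron of WWP2. The hypoxia-responsive miR-210-3p (1.07 ± 0.22) was higher, a call lost with no factors and with the haemolysis index as a covariate, and miR-145-5p (-2.43 ± 0.60), miR-27a-3p (-1.96 ± 0.23), miR-27b-3p (-1.86 ± 0.22) and miR-146a-5p (-2.13 ± 0.22) were lower. miR-34a-5p was at -0.15 ± 0.28 (adjusted p = 0.63).

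Of 16 rheumatoid arthritis literature miRNAs, 3 were higher in early OA than in controls (miR-16-5p, miR-22-3p and miR-19b-3p) and 10 lower (3 and 10 adjusted over the list alone). With total counts only, no factors, these numbers were 1 and 14, and miR-22-3p was at -0.40. Of the inflammation-responsive list 6 of 7 were lower (6 adjusted over the list alone): among them miR-155-5p (-1.58 ± 0.17), an inducible leukocyte miRNA, miR-223-3p (-2.10 ± 0.24), a myeloid and platelet miRNA, miR-146b-5p (-2.16 ± 0.31) and miR-21-3p (-3.46 ± 0.39). In the myeloid list 4 of 7 were lower (4 adjusted over the list alone; 7 with no factors; camera adjusted p = 0.092), including miR-142-3p (-2.73 ± 0.30). In the lymphocyte list 7 of 8 were lower (7 adjusted over the list alone; camera adjusted p = 0.082), including miR-342-3p (-1.85 ± 0.25). Of the 14q32 imprinted cluster, a large miRNA cluster on chromosome 14, 31 of 35 were lower (31 adjusted over the list alone; median -2.28), such as miR-382-5p (-2.17 ± 0.45), miR-432-5p (-2.14 ± 0.49) and miR-409-3p (-2.14 ± 0.44).

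Of the miR-17-92 cluster and its paralogs 8 of 10 were higher (8 adjusted over the list alone; 3 higher and 2 lower with no factors). In the liver list miR-192-5p (1.80 ± 0.35) and miR-194-5p (1.87 ± 0.37) were higher (2 adjusted over the list alone; 2 higher and 3 lower with no factors), but at -0.25 and -0.67 with the haemolysis index as a covariate, and miR-122-5p was at -0.25 ± 0.42 (adjusted p = 0.59). The let-7 and miR-98 family divided, with 4 higher and 4 lower (4 and 5 adjusted over the list alone; 1 and 8 with no factors, 4 and 2 with upper-quartile factors), let-7b-5p at 1.36 and let-7e-5p at -1.91. The miR-29 family had 2 higher and 2 lower (0 and 3 with no factors), and the miR-30 family 2 and 3 (0 and 6 with no factors, 3 and 2 with upper-quartile factors), with the same numbers adjusted over each list alone. In the muscle list 2 of 4 were lower (2 adjusted over the list alone; 4 with no factors), and in the epithelial list 2 of 4 (1 adjusted over the list alone; 3 with no factors, and 1 lower and 1 higher with upper-quartile factors). The vascular and mesenchymal list had 1 of 10 higher and 4 lower (0 and 4 adjusted over the list alone; 0 and 8 with no factors). The neural list had 1 of 5 higher, miR-7-5p, and 2 lower (1 and 4 with no factors), with the same numbers adjusted over the list alone.

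Against the other miRNAs, camera with its preset correlation called 6 of 18 lists between early OA and control. Erythrocyte (adjusted p = 1.5e-09) and the miR-17-92 cluster and its paralogs (adjusted p = 0.00017) were higher. Platelet (adjusted p = 0.00059), 14q32 (adjusted p = 0.014), inflammation-responsive (adjusted p = 0.018) and circulating early knee OA candidates (adjusted p = 0.044) were lower. Some of these lists share members. The 6 calls were lost with an estimated correlation: adjusted p = 0.079 for erythrocyte, 0.78 for 14q32 and 0.15 for the other 4 with an estimated correlation. With the haemolysis index as a covariate the number of miRNAs changed between early OA and control was 97, 27 higher and 70 lower. The indices of early OA and control samples overlap only from 1.21 to 2.16, which limits that fit.

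Among the 44 controls alone, 70 of 368 miRNAs, without the 2 that make the index, changed with the haemolysis index in edgeR's test, 44 upward and 26 downward. Across the 368 this slope correlated with the early OA fold change (r = 0.61, Spearman's rho = 0.60; miRNAs are not independent replicates). The median slope per unit of the index was 0.43 (log2) for the erythrocyte list without miR-451a, 0.44 for the liver list and -0.06 for the platelet list. The index is noisy in some controls, since miR-451a had only 3 counts in control 4.

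**Figure D2:**
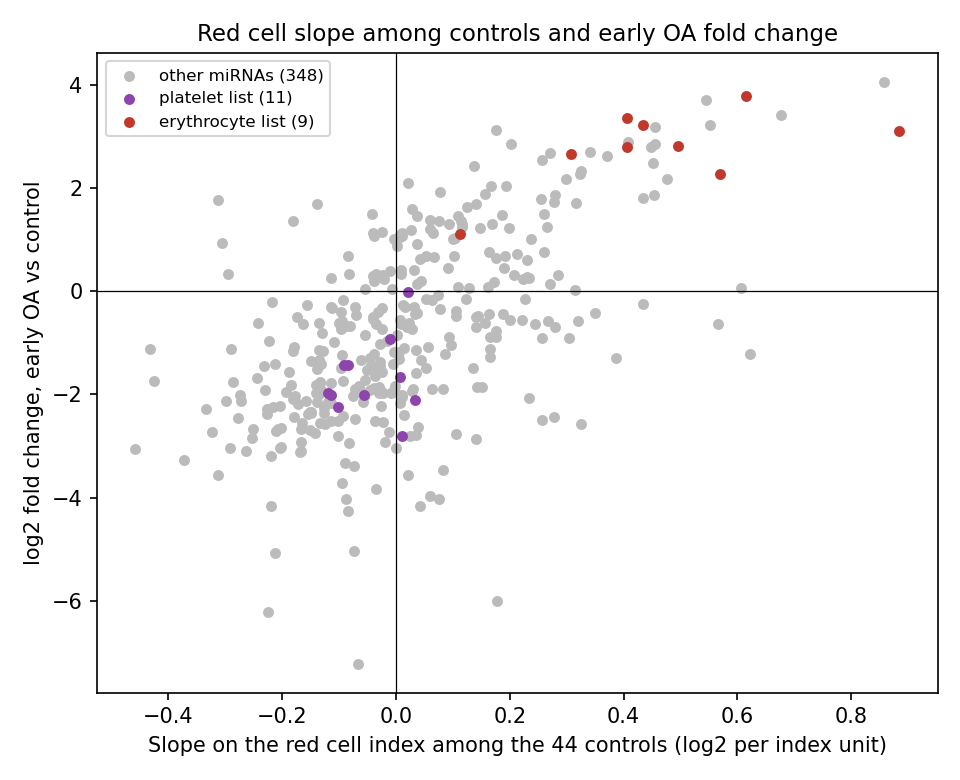
Each point is 1 of 368 miRNAs: on the horizontal axis its change per unit of the haemolysis index among the 44 controls (log2), on the vertical axis its log2 fold change between early OA and control. The erythrocyte list has a median slope of 0.43 and the platelet list of -0.06.

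Between early RA and control, 10 miRNAs were higher and 1 lower. miR-183-5p (2.24 ± 0.47) had the smallest p (± SE, n = 6 against 44; edgeR adjusted p = 0.004, 5 of 6 samples above the control median), followed by miR-1294 (1.47 ± 0.32), let-7b-5p (0.74 ± 0.17) and miR-7-5p (1.08 ± 0.26). The other higher ones were miR-486-3p (1.09 ± 0.28), miR-6815-5p (1.98 ± 0.50), miR-1180-3p (1.51 ± 0.40), miR-196b-5p (1.08 ± 0.28), miR-486-5p (1.24 ± 0.33) and miR-20b-5p (0.96 ± 0.28), each above the control median in 4 or 5 of 6 samples. Directions turned for miR-183-5p (-0.14) and miR-486-5p (-0.06) without early RA samples 1 and 2 together, and for miR-196b-5p (-0.50, adjusted p = 0.798) with every library thinned to the smallest total. Normalised let-7b-5p was 81808 ± 35051 CPM in early RA (SD, n = 6) and 48998 ± 10861 in controls (SD, n = 44). Normalised miR-486-5p was 20051 ± 19239 against 8506 ± 4995. miR-1250-5p was lower, at 1.47 ± 1.59 CPM against 5.26 ± 2.88 (log2 fold change -1.81 ± 0.50, edgeR adjusted p = 0.02, 6 of 6 samples below the control median). Of 370 miRNAs 61 had an unadjusted p under 0.05, and the median log2 fold change was -0.07 with TMM factors and -0.30 with total counts only, no factors.

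Of the erythrocyte list 3 of 10 were higher in early RA than in controls, miR-183-5p, miR-486-3p and miR-486-5p (5 adjusted over the list alone; median 0.87), beside an index difference of 0.98. miR-16-5p was at 0.69 ± 0.23 (adjusted p = 0.093) and miR-451a at 0.63 ± 0.50 (adjusted p = 0.59). Camera called this list (adjusted p = 6.2e-05) and the let-7 and miR-98 family (adjusted p = 0.024). Both calls were lost, with adjusted p = 0.5 for each with an estimated correlation. In the let-7 and miR-98 family 1 of 9, let-7b-5p, was higher (1 adjusted over the list alone; 0 with no factors). In the miR-17-92 cluster and its paralogs it was 1 of 10, miR-20b-5p (2 adjusted over the list alone; 0 with upper-quartile factors), and in the neural list 1 of 5, miR-7-5p (1 adjusted over the list alone).

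In edgeR 0 tested members passed in the circulating early knee OA candidate, cartilage and chondrocyte, rheumatoid arthritis literature, platelet, myeloid, lymphocyte, liver, muscle, epithelial, vascular and mesenchymal, miR-29, miR-30, 14q32 and inflammation-responsive lists between early RA and control. Adjusted over each list alone, 1 passed, the muscle miRNA miR-206 (-2.24 ± 0.74, adjusted p = 0.093 over all). Of the rheumatoid arthritis literature list, miR-146a-5p was at -0.11 ± 0.25 (adjusted p = 0.87), miR-155-5p at -0.23 ± 0.20 (adjusted p = 0.63), miR-223-3p at -0.49 ± 0.29 (adjusted p = 0.41) and miR-21-5p at 0.45 ± 0.19 (adjusted p = 0.21). The platelet miRNA miR-126-3p was at -0.28 ± 0.16 (adjusted p = 0.39).

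The number of miRNAs changed between early RA and control rested on early RA samples 1 and 2, the 2 with the highest haemolysis index. Without early RA replicate 1 edgeR called 0 (49 at an unadjusted p under 0.05), without early RA replicate 2 it called 1, and without early RA replicate 5 or without early RA replicate 6 it called 19. With the haemolysis index as a covariate, with total counts only, no factors, and by limma-voom with quality weights the number was 0 (60, 85 and 64 at an unadjusted p under 0.05), and by the DESeq2 Wald test 18.

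**Figure D3:**
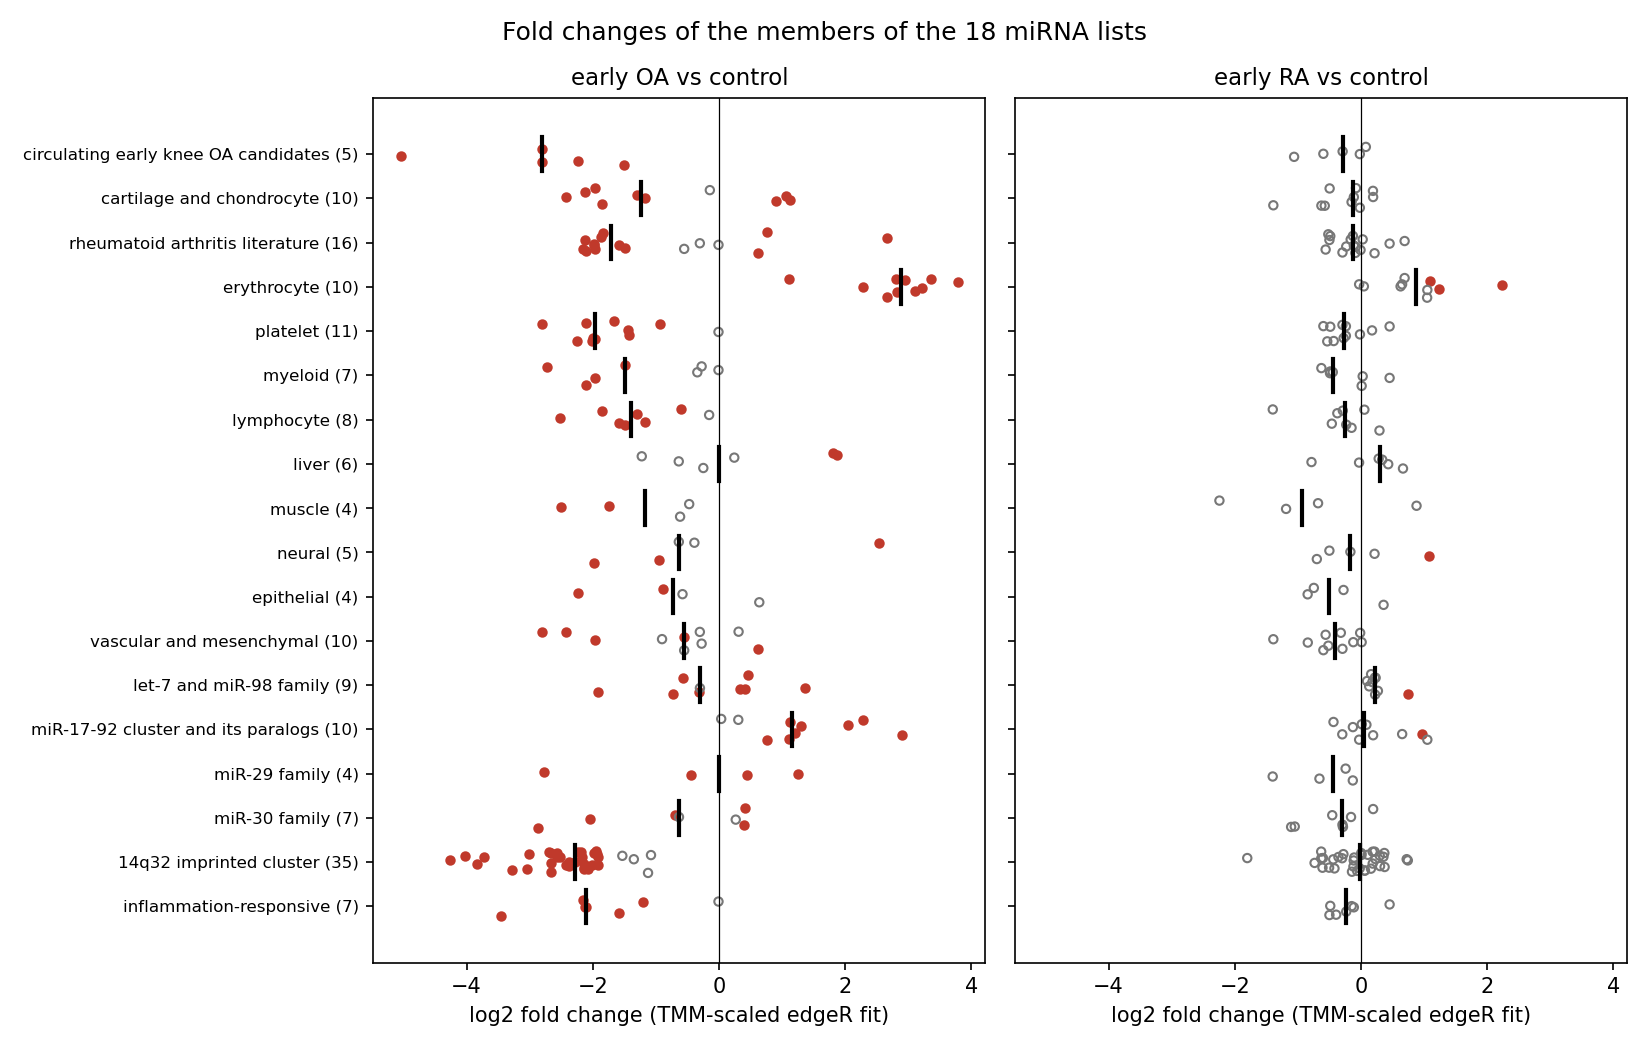
Each point is the log2 fold change of 1 list member in the TMM-scaled edgeR fit, for early OA (left) and early RA (right) against control. Filled points have an adjusted p under 0.05, the black bar is the list median and the number of tested members is in brackets, with 10 of 10 erythrocyte members filled on the left and 3 on the right.

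Between early RA and early OA, platelet and 14q32 miRNAs were higher and red cell miRNAs lower in early RA. Above the early OA median in 6 of 6 samples were miR-24-3p (1.78 ± 0.18) (edgeR adjusted p = 1.5e-12), miR-3074-5p (1.91 ± 0.20), miR-28-3p (2.23 ± 0.25), miR-181c-3p (3.68 ± 0.41), miR-126-3p (1.39 ± 0.17), miR-30e-3p (1.89 ± 0.23), miR-744-5p (2.29 ± 0.29) and miR-26a-5p (1.75 ± 0.22) (± SE, n = 6 against 12). So were miR-151a-3p (1.76 ± 0.23), miR-652-3p (1.63 ± 0.22), miR-760 (3.86 ± 0.52) and miR-548ax (2.63 ± 0.36). The sizes for miR-760, miR-548ax and miR-181c-3p depend on the prior count, since they had no count in 6, 4 and 6 of 12 early OA libraries. Below the early OA median in 6 of 6 samples were miR-16-5p (-1.97 ± 0.31) (edgeR adjusted p = 3.3e-07), miR-486-3p (-2.26 ± 0.39), miR-660-5p (-1.69 ± 0.29), miR-185-5p (-1.12 ± 0.19), miR-15a-5p (-2.08 ± 0.38) and miR-20b-5p (-1.93 ± 0.39). So were miR-3143 (-2.13 ± 0.43), miR-29c-3p (-1.49 ± 0.32), miR-20a-5p (-1.12 ± 0.24), miR-25-3p (-1.39 ± 0.30), miR-93-5p (-0.93 ± 0.20) and miR-101-3p (-1.66 ± 0.37). In total 216 of 370 differed, 152 higher and 64 lower (237 at an unadjusted p under 0.05; median 0.66). With upper-quartile factors the number of miRNAs changed split into 134 and 86, and with total counts only, no factors, into 214 and 19 (median 1.51).

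By list, 9 of 10 erythrocyte miRNAs were lower in early RA than in early OA (9 adjusted over the list alone), beside an index difference of -4.59. Higher were 10 of 11 platelet miRNAs (11 adjusted over the list alone), 29 of 35 of the 14q32 imprinted cluster (31 adjusted over the list alone) and 6 of 7 inflammation-responsive miRNAs (7 adjusted over the list alone). So were 5 of 5 circulating early knee OA candidates (5 adjusted over the list alone), among them miR-335-5p (1.59 ± 0.31) and miR-199a-5p (2.21 ± 0.35). Of the rheumatoid arthritis literature list 10 of 16 were higher and 2 lower (11 and 2 adjusted over the list alone), with miR-146a-5p (2.02 ± 0.28), miR-155-5p (1.35 ± 0.23) and miR-223-3p (1.62 ± 0.31) higher. Of the cartilage and chondrocyte list 4 were higher and 3 lower (5 and 3 adjusted over the list alone; 7 and 0 with no factors), with miR-140-3p at -0.99 ± 0.28.

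The miR-17-92 cluster and its paralogs had 6 of 10 lower (6 adjusted over the list alone; 2 with no factors, 9 with upper-quartile factors). The myeloid list had 4 of 7 higher (7 with no factors) and the lymphocyte list 6 of 8, with the same numbers adjusted over each list alone. The let-7 and miR-98 family had 5 of 9 higher and 1 lower, the same adjusted over the list alone, but 7 and 0 with no factors and 2 and 2 with upper-quartile factors. In the liver list miR-192-5p and miR-194-5p were lower (0 adjusted over the list alone; 0 lower and 1 higher with no factors). Of the neural list 2 of 5 were higher and 1 lower, and of the miR-30 family 2 of 7 higher and 1 lower (4 and 0 with no factors, 2 and 3 with upper-quartile factors). Of the vascular and mesenchymal list 2 of 10 were higher (5 with no factors), of the muscle and epithelial lists 1 of 4 each, and of the miR-29 family 1 of 4 was lower (with upper-quartile factors, 1 vascular and mesenchymal and 1 muscle miRNA were also lower, and 2 of the miR-29 family). In these 6 lists the numbers were the same adjusted over the list alone.

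Camera called 7 lists between early RA and early OA: erythrocyte (adjusted p = 7.4e-06) and the miR-17-92 cluster and its paralogs (adjusted p = 0.00015) lower, and platelet, 14q32, inflammation-responsive, circulating early knee OA candidates and rheumatoid arthritis literature higher (adjusted p = 0.00015, 0.0052, 0.0072, 0.024 and 0.034). All 7 calls were lost, with adjusted p = 0.7 for 14q32, 0.4 for rheumatoid arthritis literature and 0.13 for the other 5 with an estimated correlation. With the haemolysis index as a covariate the number of miRNAs changed between early RA and early OA was 42, 36 higher and 6 lower. The indices of early RA and early OA samples overlap only from 1.21 to 1.57, which limits that fit. With the sample number as a replicate block over samples that share a number, the number changed was 114.

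Across the 370 miRNAs, the fold changes of early OA and of early RA against control correlated with r = 0.56 (Spearman's rho = 0.51, covariance 0.648; miRNAs are not independent replicates). Both comparisons share the 44 controls. Simulated groups with no change gave a mean r of 0.15 and a covariance of 0.0245, and controls split at random into 22 and 22, 1 set for each comparison, gave a mean r of 0.54 and a covariance of 0.645 over 20 splits. The simulation drew each miRNA independently, while the first principal component of the real samples held 41.1% of the variance. Its values leave out miRNAs that move together and do not bound the agreement that chance would give. The 10 miRNAs higher in early RA, such as miR-486-5p, miR-183-5p and let-7b-5p, were also higher in early OA, where 2.57 would be shared by independent lists. miR-1250-5p was lower in both, where 0.527 would be shared. With the controls split, a mean of 6.55 higher and 0.75 lower miRNAs were shared, where 1.81 and 0.408 would be. Shared controls and miRNAs that move together make the lists not independent.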

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

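The tests of platelet against liver miRNAs and of abundant platelet miRNAs, the slopes of the liver list among controls, the antisense pairs without miR-486, the fit of early RA and control alone with the index, and the fits without early RA samples 1 and 2 together, were chosen after the result was seen.

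Of 370 miRNAs, 290 differed between early OA and control, and 1 of 100 splits of these samples, the real one, gave as many, the highest other giving 98. This argues against chance, but 1 of 100 is the smallest share these splits can give, so they do not exclude it. Lower depth as the whole cause is argued against, since 81.0% of the calls were kept in direction after every library was thinned to the smallest total. More red cell RNA in early OA plasma may contribute: the slope on the haemolysis index among controls alone correlated with the early OA fold change at r = 0.61. Whether it is the whole cause, or less platelet RNA contributes, stays open: platelet miRNAs fell below liver miRNAs by -2.16 (95% bootstrap interval -2.78 to -1.54) and 100% of 9 abundant ones lay below the liver median, but among controls 5 of 6 liver miRNAs rose with the index. Over its difference of 5.56 the median slopes give a gap of -2.78, though not the level of either list (liver 2.47 against an observed median of -0.004, platelet -0.31 against -1.97), and 10 of 12 early OA indices lie above the highest control. The disease itself stays open and untested, as does blood handling, which is not given per sample in the sources used here.

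Between early RA and control 11 miRNAs differed, and 2 of 100 splits gave as many, the highest other giving 11. This argues against chance at a share of 0.05 but does not exclude it, since another split gave as many. The number was 0 without early RA samples 1 and 2 together. More red cell RNA in part of the early RA samples may account for part of these calls: with the haemolysis index as a covariate 0% were kept, and their median absolute log2 fold change went from 1.24 to 0.84 (without early RA samples 1 and 2 together, to 0.35) while the median SE went from 0.323 to 0.301. In a fit of early RA and control alone with the index, 1 call was kept, let-7b-5p (0.63 ± 0.15, adjusted p = 0.0345), and the median was 0.68. Across 368 miRNAs, the slope on the index among controls alone correlated only weakly with the early RA fold change (r = 0.23, Spearman's rho = 0.10). Some folds kept most of their size with the index as a covariate. These were let-7b-5p (0.74 ± 0.17 to 0.67 ± 0.17), miR-1250-5p (-1.81 ± 0.50 to -1.68 ± 0.48) and miR-196b-5p (1.08 ± 0.28 to 0.995 ± 0.30). Their unadjusted p of 0.000217, 0.000934 and 0.0015 no longer passed adjustment in the fit of all groups. Without early RA samples 1 and 2 together the folds were 0.56, -1.28 and 0.78. Among controls let-7b-5p rose with the index (slope 0.11, edgeR adjusted p = 0.0173), while miR-1250-5p (-0.07) and miR-196b-5p (0.02) did not pass. The index is noisy, resting on 32 and 61 counts in early RA sample 4, so the covariate may correct too little. Whether the index accounts for these miRNAs stays open, and miR-196b-5p was at -0.50 with every library thinned to the smallest total. The disease itself stays open and untested.

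Between early RA and early OA 216 miRNAs differed, and 1 of 100 splits, the real one, gave as many, the highest other giving 84. This argues against chance, but again 1 of 100 is the smallest share possible. The comparison of early RA with early OA is also the test of whether the differences of early OA and of early RA from control differ, which they did for 216 miRNAs.

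For 7 pairs of miRNAs from opposite strands of 1 locus, such as miR-24-3p and miR-3074-5p, the median r across samples was 0.94 and the median SD of the log2 ratio 0.338, against a median r of 0.07 for 1000 random pairs. Over the 7 pairs, the median r of 0.9 or more and the limit on the SD that were set beforehand were both met. Whether reads of a miRNA were counted for its antisense partner still stays open. The pair miR-486-5p and miR-486-3p also has the names of the 2 arms of 1 hairpin. Without that pair, a check chosen after the result was seen, the median r was 0.88, below 0.9. The pair miR-103a-3p and miR-103b had r = 0.72 and log2 fold changes of 0.34 and 1.31 between early OA and control. Transcription from both strands stays open and untested.

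Dixon's test, which flags about 1 in 20 groups by chance, was run on 47 sets of early RA values and marked 5. They are log2 CPM of -0.34 for miR-1260b, -0.34 for miR-671-3p, 3.26 for miR-140-5p and -0.34 for miR-145-5p in early RA sample 4, and of 16.75 for let-7f-5p in early RA sample 3. A value of -0.34 stands for 0 counts plus the prior count, not for a measured level. Sample 4 has the lowest total of the early RA libraries, 444861 counts.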

How the results depend on the processing

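The alternatives that leave out libraries under 500000 counts, early RA samples 1 and 2 together or controls with an index above 0, that thin every library, or that keep samples sharing a number with no replicate block were chosen after the result was seen. Where no cause is named, the cause was not tested.

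The number of miRNAs changed between early OA and control was 97 with the haemolysis index as a covariate against 290, and ran from 266 to 292 with each replicate left out. It was lowest without early RA replicate 5 or 6, where TMM takes control 4 in place of control 31 as its reference library, the median log2 fold change moves from -0.91 to -0.43 and the calls split into 111 higher and 155 lower.

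The number of miRNAs changed between early RA and control, 11, ran from 0 to 19 with each replicate left out: 0 without early RA replicate 1, 1 without early RA replicate 2, and 19 without early RA replicate 5 or without early RA replicate 6. In edgeR it was 0 with total counts only, no factors (85 at an unadjusted p under 0.05), 0 with the haemolysis index as a covariate (60) and 0 without early RA samples 1 and 2 together (49), and it was 0 by limma-voom with quality weights (64). It was 18 by the DESeq2 Wald test, 20 with at least 10 CPM in at least 6 samples, 26 without libraries under 500000 counts (5 control, 4 early OA and 1 early RA) and 25 without the 6 controls with an index above 0.

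No label pairs samples of different groups, which were treated as coming from different people. Pairing them by a replicate block over samples that share a number gave 0 miRNAs changed between early RA and control in edgeR (28 at an unadjusted p under 0.05), and the samples that share a number, with no replicate block, also gave 0 (40), so the smaller set of samples and not the block ends the call. The replicate block gave 114 between early RA and early OA (144 on the same samples with no replicate block) and 229 between early OA and control (247 with no replicate block). The number of miRNAs changed between early RA and early OA was 42 with the haemolysis index as a covariate against 216, and ran from 187 to 230 with each replicate left out. The indices of these 2 groups overlap only from 1.21 to 1.57, which limits the fit with the covariate.

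For the miRNA list tests, camera with an estimated correlation called 0 lists in each of the 3 comparisons, and fry called 14 between early OA and control, 0 between early RA and control and 14 between early RA and early OA, against 6, 2 and 7. With the haemolysis index as a covariate camera called 1 list between early RA and control.

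Directions turned for these log2 fold changes. Between early OA and control with total counts only, no factors: miR-140-3p -0.0875, miR-22-3p -0.40, miR-17-5p -0.998, miR-10b-5p -0.32, let-7g-5p -0.62 and let-7i-5p -0.61. Between early OA and control with the haemolysis index as a covariate: miR-451a -0.59, miR-144-3p -0.16, miR-192-5p -0.25, miR-194-5p -0.67, miR-1-3p 0.77 and miR-10b-5p -0.0720. miR-21-5p between early OA and control was 0.47 without early RA replicate 5, 0.47 without early RA replicate 6 and 0.38 without libraries under 500000 counts, and ran from -0.095 to 0.47 with each replicate left out. Between early RA and control, miR-196b-5p was -0.50 with every library thinned to the smallest total, and without early RA samples 1 and 2 together miR-183-5p was -0.14 and miR-486-5p -0.0592. Between early RA and early OA, let-7b-5p was 0.11 with total counts only, no factors, miR-451a 0.45 and miR-144-3p 0.16 with the haemolysis index as a covariate, and miR-122-5p -1.97 without early RA samples 1 and 2 together. miR-451a is the numerator of the haemolysis index, so its values of -0.59 and 0.45 with that covariate follow from the index and test nothing.

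The number of miRNAs detected differed by -8.80 between early RA and control when thinned to the smallest total (exact permutation p = 0.0336), against -45.5 at full depth. The agreement of fold changes of early OA and early RA with control had r = 0.61 over only miRNAs with a mean of at least 100 CPM, against 0.56.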

Other observations

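The tests in this part were chosen after the result was seen. The hairpins miR-197, miR-32, miR-425, miR-127, miR-323a and miR-431 are named because of their values.

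For 72 hairpins both arms were tested between early OA and control, and the log2 fold changes of the arms correlated with r = 0.67. Both arms passed for 50 hairpins, in the same direction for 43 and in opposite directions for 7: let-7d, miR-140, miR-197, miR-29c, miR-30e, miR-32 and miR-425. These directions depend on the scaling. With total counts only, no factors, the median log2 fold change of all tested miRNAs was -1.96 against -0.91 with TMM factors, and miR-140-3p was at -0.09. Over all 72 hairpins, the log2 ratio of the 5p to the 3p arm differed between early OA and control for 38, lower for 8 and higher for 30 (permutation tests adjusted over 72; 40 at an unadjusted p under 0.05). These 38 hold 17 of the 43 and 6 of the 7, such as miR-140 (-2.93) and miR-30e (2.61), each with adjusted p = 4.8e-05, from the smallest p that 100000 resamples can give. For let-7d the difference was -0.65 (adjusted p = 0.184). A ratio of arms does not show which arm moved. It was taken from log2 CPM with a prior count, so an arm with few or no counts in a library sits near a floor. For miR-127, miR-323a and miR-431, among the 38, the ratio moved opposite to the gap between the fitted log2 fold changes of the arms. The 38 calls therefore need not all be shifts between the arms.

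The first principal component of the log2 CPM held 41.1% of the variance and correlated with the haemolysis index at r = 0.92 and with the log2 total count at r = -0.61. The next held 11.7%. Both correlations pool all 62 samples, and early OA differed from controls in the index and in the total count. They therefore do not separate the index or the depth from the group.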
